A study of Mus musculus with 2 samples.

How the data were processed

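DNase-seq marks open chromatin: nuclei are treated with the nuclease DNase I, and the short fragments it releases are sequenced, so that reads pile up where the DNA is accessible. The series holds 2 libraries from cerebellum of female B6CASTF1/J mice aged 8 to 10 months, a first-generation hybrid between laboratory black mice and the wild-derived CAST strain. Each library was made from a separate pool of 2 biosamples, per the labels, which number them as biological replicates 1 and 2. Both belong to 1 group, so the design holds no comparison between conditions, and the questions asked were where chromatin was open, which genes and sequence motifs these places carried, and how closely the 2 pools agreed.

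Per library, the authors deposited a pair of peak lists, a list of footprints (short protected stretches inside accessible DNA) and a track of false discovery rates, all on the mouse build mm10, per the labels. The aligner, the peak caller and the footprint caller are not given in the sources used here. The peak lists carry the authors' signal per peak, a value that is never negative, and peaks and footprints were called in each library separately, per the labels, which assign each file to a library. Every signal value was a whole multiple of a fixed step, 0.00783 in replicate 1 and 0.00618 in replicate 2, within a tolerance of 0.01 steps. The step is read as 1 count scaled to sequencing depth, which is an inference from the values and is used only to judge depth. The deposited track gives a q-value-like false discovery rate per stretch of bases, listed by the authors up to 0.05. All peaks of the longer list of a library touched a stretch at a rate of 0.05 or less, and all peaks of the shorter list touched one at 0.001 or less. The longer list was used for all main results, and the shorter list as an alternative. That choice was made after the list lengths had been seen and before any result was computed.

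Coordinates were compared with the GRCm38.p6 sequence, which is the same build, and all peaks lay within its chromosome lengths. Transcription starts, exons and coding sequence came from the GENCODE M21 basic annotation, with 55413 genes, of which 21938 are protein-coding, and 77221 distinct transcription starts. A peak belonged to the feature at its centre, in the order promoter (1000 bp either side of a transcription start), 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic. The ratio to the share of bases carries a Poisson interval at 95% in the tables, which covers counting error only.

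A peak counted as shared when it overlapped a peak of the other library by at least 1 bp. Chance overlap came from 100 random placements of the same widths on the same chromosomes, and for footprints from 100 placements within the same peaks. Signals were compared as log2 values over merged regions called in both libraries. The interval of that correlation came from 1000 bootstraps over blocks of 5 Mb, and no p is given because regions are not replicates.

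Before the data were examined, 24 gene lists were fixed: cell types of the cerebellum (granule neuron, Purkinje cell, GABA interneuron, unipolar brush cell, Bergmann glia and astrocyte, oligodendrocyte lineage, microglia, endothelial and mural cell, choroid plexus and ependyma), other tissues (forebrain neuron, liver, muscle, lymphocyte, erythroid, germ line, keratinocyte), positional genes (hindbrain and midbrain patterning, posterior Hox) and general classes (synaptic, immediate early, circadian clock, housekeeping, imprinted, escape from X inactivation). Of 450 symbols, 448 were found in the annotation. For each list, the share of genes with a promoter peak in both libraries was ranked among 10000 random lists of protein-coding genes, matched on the decile of observed/expected CpG around the transcription start. The median number of shared non-promoter peaks per 100 kb, over the gene body plus 10 kb either side, was ranked among 10000 random lists matched on gene length. Random lists were drawn without replacement within each decile, which permutes list membership among matched genes. Two-sided permutation p-values were adjusted by the Benjamini-Hochberg method over the 24 lists. The smallest unadjusted p that 10000 lists allow is 0.0002. These tests compare lists within this tissue, and genes are not replicates.

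For each of 28 consensus sequences, also fixed beforehand, the share of shared distal peaks (centre over 2500 bp from any transcription start) with a match on either strand within 75 bp of the centre was divided by the share in windows 2000 bp to either side that overlapped no peak, resampled to the same GC content in bins of 2 percentage points. Intervals at 95% came from 1000 bootstraps over blocks of 5 Mb. A motif was called when the interval excluded 1. The added condition that no motif is called where both sets hold 3 matches or fewer was set after seeing the data, when HNF1 had passed with 0 matches in peaks and 1 in flanks. In footprints, 10 bp were added either side, and the control was a window of the same width inside the same peak that overlapped no footprint, not matched on GC.

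The genes named were set by a rule written before the data were examined: per list, up to 4 members with the highest mean signal at a promoter peak called in both libraries and up to 3 members, in list order, with no promoter peak in either; the 10 protein-coding genes with the strongest promoter peak; the genes nearest to the 10 strongest distal regions; each called motif; and each called list. Not every gene that the rule takes is printed. Genes named outside that rule are marked as chosen after their values were seen.

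The list test was checked on simulated data: 2 of 2 planted lists were called and 0 of 22 unplanted ones. The planted lists had a peak at all or at none of their genes, so the check does not cover shares in between. In the motif test, run on 30000 simulated windows, a planted AP-1 site was found in 12.34% of windows against 12.4% expected, and the ratios of unplanted motifs in over 1% of windows lay between 0.902 and 1.04. Alternatives changed the overlap rule, the peak list, the signal threshold, the promoter window, the transcription starts used, the matching, the gene domain, the control windows and the motif window, and left out each replicate in turn. Sequence copies were searched with BLAST+ 2.17.0. All other steps used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. The deposited text notes beside the files were read for the origin of the files only, and no value was taken from them. The flanks matched on CpG number, the groups of signal used for the overlap, and the comparisons between the pools by gene and gene list, and the look-up of the strongest peak, were chosen after seeing the data. Overlaps were computed with NumPy in place of the planned bedtools, by the same rule. Means are given with the SD over the 2 libraries.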

Results

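Chromatin accessibility was mapped by DNase-seq in the cerebellum of adult female mice of the B6CASTF1/J hybrid strain, in 2 libraries from separate pools of 2 biosamples each. In replicate 1, 104660 peaks with a median width of 207 bp covered 23.9 Mb, or 0.904% of the genome. In replicate 2, 120108 peaks with a median width of 200 bp covered 27.7 Mb, or 1.04% of the genome. The median signal of a peak was 0.9003 in replicate 1 and 0.649 in replicate 2, which is 115 and 105 signal steps. A step is the smallest unit of the authors' signal. The shorter peak lists held 67013 and 77605 peaks. Bases at a false discovery rate of 0.05 or less spanned 40.6 Mb in replicate 1 and 48.4 Mb in replicate 2.

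Which regions were open in both pools was asked first. Of the peaks of replicate 1, 76.9% overlapped a peak of replicate 2, and 66.9% of the peaks of replicate 2 overlapped one of replicate 1, a mean of 71.9% ± 7.01 (SD, n = 2). Random placements of the same widths gave at most 2.27%, and 0 of 100 placements reached the observed share. The share rose with peak strength: in 4 equal groups of increasing signal it was 49.4%, 70.9%, 88.9% and 98.9% in replicate 1, and 30.6%, 55.6%, 83.3% and 98.7% in replicate 2. Across the 74338 merged regions called in both libraries, log2 signals correlated with Pearson's r = 0.96 (95% interval 0.96 to 0.97) and Spearman's rho = 0.959. These are correlations across regions, which are not independent replicates. Signals in replicate 1 were higher by a median of 0.30 on the log2 scale (1.23-fold), so that most SDs quoted for single genes hold this common offset. Of the regions, 97.3% lay within 2-fold of that median ratio.

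Peaks called in a single library had lower median signals than shared ones. They numbered 24222 in replicate 1 (23.1%), with a median signal of 0.431 against 1.20 for shared peaks, and 39704 in replicate 2 (33.1%), with a median of 0.334 against 1.02. Their median height was 55.0 and 54.0 signal steps, though 26.6% and 25.8% of them were in the shorter lists and 13.1% and 13.5% lay above the median signal of their list. Promoters took 19.4% and 15.9% of these peaks, against 32.0% and 31.9% of shared peaks. With 1 library on each side, no test of a difference between the pools was possible. The share of peaks counted as specific to a library was 28.1% ± 7.01 (SD, n = 2) on average, 43.3% when 50% reciprocal overlap was required and 18.9% when no peak within 500 bp was allowed.

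Open chromatin was concentrated at promoters. Peaks centred within 1000 bp of a transcription start made up 27.8% ± 1.75 of all peaks (SD, n = 2), 6.36 ± 0.399 times the share of bases there. Coding exons held 4.23% ± 0.747 of peaks, 3.85 ± 0.680 times their share of bases, and 3′ UTRs held 1.96% ± 0.104, or 1.67 ± 0.0889 times. Introns held 38.8% ± 1.60, close to their share of bases of 38.9%. Intergenic sequence held 26.2% ± 0.977, which is 0.487 ± 0.0182 times its share. Of 21911 protein-coding genes, with each gene symbol used once, 13196 (60.2%) had a promoter peak in both libraries. The share rose with CpG content around the start, from 5.48% in the lowest decile to 96.1% in the highest.

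The strongest peak of each library, looked up after the values were seen, overlapped the ribosomal RNA gene CT010467.1 (chromosome 17, from 39846781), with a signal of 85.9 in replicate 1 and 65.5 in replicate 2, and lay 58 and 38 bp from a start of the non-coding gene Gm42418. Among protein-coding genes, the strongest promoter peak belonged to Dynlt1b, which encodes a dynein light chain (mm10 chromosome 17, 6430001 to 6430180), with a signal of 36.8 ± 10.95 (SD, n = 2). It was followed by Hjurp, a chaperone of centromeric histones, with 25.6 ± 6.17, and by a peak at chromosome 14, 54686601 to 54686940, shared by the neighbouring starts of 1700123O20Rik and Acin1, with 24.7 ± 8.06. Bahcc1 (22.3 ± 8.93), Wwox (22.1 ± 3.72), Nup107 (21.7 ± 5.70), Dnpep (21.3 ± 8.74), Nup153 (21.2 ± 8.09) and 4930535I16Rik (20.5 ± 4.49) completed the 10 genes. Nup107 and Nup153 encode parts of the nuclear pore. Copies of the strongest peak and of these promoter regions elsewhere in the genome were not searched. Their signals may therefore include reads from repeated sequence.

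The strongest distal region lay in the 3′ UTR of Lars2, a mitochondrial leucyl-tRNA synthetase (chromosome 9, 123461881 to 123462140), with a signal of 38.4 in replicate 1 and 37.5 in replicate 2. Its nearest protein-coding start is that of Limd1, 16.7 kb away. An intergenic region 109.6 kb from Gm8797 (chromosome 3, 5860361 to 5860530) had signals of 37.3 and 29.1, and an intergenic region 21.6 kb from Igf2bp3 (chromosome 6, 49236421 to 49236620) had 32.4 and 26.3. Both of these have copies elsewhere in the genome sequence. The region nearest to Cox14 lay in the 3′ UTR of Cers5 (chromosome 15, 99735661 to 99736060), with 28.6 and 29.0. The others were an intronic region of Vps37c (25.4 and 17.9), a non-coding exon region near C87436 (17.9 and 13.2) and intergenic regions nearest to Txn2 (23.1 and 16.3), Foxk1 (19.4 and 14.1), Ptma (18.9 and 13.2) and Zfp239 (17.7 and 12.8).

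Granule neurons are the most abundant cells of the cerebellum, and all 20 of 20 granule neuron genes had a promoter peak in both libraries, against a mean of 69.3% in CpG-matched random lists (adjusted permutation p = 0.00096, gene-label permutation with Benjamini-Hochberg adjustment over 24 lists). The strongest were Cbln3, a synaptic organiser (11.2 ± 2.96, SD, n = 2, in a window that also holds a start of Khnyn), the transcription factor genes Neurod1 (8.66 ± 2.97), Zic2 (7.14 ± 1.83) and Neurod2 (6.75 ± 1.96). Housekeeping genes also stood above random lists at 20 of 20 (mean of random lists 82.1%, adjusted permutation p = 0.0315), led by Rplp0 (19.2 ± 5.64), Actb (13.7 ± 3.62), Ppia (13.0 ± 2.999) and Ywhaz (11.8 ± 3.29). Other classes were complete too, at 20 of 20 synaptic genes, 20 of 20 immediate early genes and 18 of 18 circadian clock genes, but did not pass the test in the main setting (adjusted permutation p = 0.0851, 0.0552 and 0.260), with means of random lists at 83.7%, 84.4% and 88.0%. The strongest were Syn2 (9.07 ± 2.28), Jun (14.4 ± 3.96), which responds to activity, and the clock gene Per2 (14.9 ± 4.27).

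Promoters of the posterior Hox, germ line, forebrain neuron and hindbrain and midbrain patterning lists carried peaks less often than CpG-matched lists. None of 20 posterior Hox genes, which pattern the trunk, had a promoter peak in both libraries, and 18 had one in neither, among them Hoxa5, Hoxa7 and Hoxa9, against a mean of 87.9% in random lists (adjusted permutation p = 0.00096). Of 20 germ line genes, 2 had a promoter peak in both, Tex14 (10.1 ± 1.95, in a window that also holds a start of Rad51c) and Dazl (4.80 ± 0.798), while Ddx4, Prm1 and Prm2 had none (random mean 59.7%, adjusted permutation p = 0.00096). Of 20 forebrain neuron genes, 7 had a promoter peak, among them Drd1 (1.53 ± 0.420), Lhx2 (1.23 ± 0.0336) and Tbr1 (0.685 ± 0.0603), and Dlx1 and Dlx5 had none in either library (random mean 77.1%, adjusted permutation p = 0.00096). With the outermost start of each gene alone, the forebrain share was 20%, still called below random lists (adjusted permutation p = 0.00096). Of 20 hindbrain and midbrain patterning genes, 9 had a promoter peak, led by En2 (7.62 ± 1.99), Meis1 (6.52 ± 1.83), Egr2 (2.498 ± 0.220) and En1 (1.67 ± 1.12), whereas Pax2, Pax8 and Lmx1b had none (random mean 83.1%, adjusted permutation p = 0.00096).

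Rarer cell types of the cerebellum were represented unevenly. Of 20 endothelial and mural cell genes, 6 had a promoter peak in both libraries (random mean 60.2%, adjusted permutation p = 0.0096), with low signals at Vtn (0.672 ± 0.268), Foxc1 (0.662 ± 0.149), Esam (0.627 ± 0.187) and Kcnj8 (0.330 ± 0.0207) and none at Cldn5, Pecam1 and Tek. Of 18 GABA interneuron genes, 9 had one (random mean 74.7%, adjusted permutation p = 0.0384), led by Prkcd (1.40 ± 0.243), Nxph1 (0.879 ± 0.107), Pvalb (0.837 ± 0.0123) and Tfap2a (0.806 ± 0.222), and Slc32a1, Tfap2b and Pax2 had none. For Purkinje cells, the output neurons of the cerebellar cortex, 15 of 20 genes had a promoter peak (adjusted permutation p = 0.602). Itpr1 (8.71 ± 2.78), Lhx1 (6.18 ± 1.64), Rora (3.86 ± 1.04) and Pcp4 (3.40 ± 0.331) were the strongest, while the Purkinje markers Pcp2, Ppp1r17 and Skor2 had no promoter peak in either library. The Rora peak of replicate 1 (chromosome 9, 69289681 to 69289960) lay at an inner start, not at the outermost one (68653786). With the outermost start of each gene alone, the Purkinje share was 55%, against 75% in the main setting. Its percentile among random lists was 7.5 there, against 83.4 (adjusted permutation p = 0.431, not called).

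The remaining cerebellar lists did not pass the test in the main setting. Bergmann glia and astrocyte genes had promoter peaks at 13 of 20 (adjusted permutation p = 1), led by Glul (5.57 ± 0.952, in a window that also holds a start of Teddm2), Aldoc (4.41 ± 1.04), Nfib (4.35 ± 0.0398) and Kcnj10 (3.16 ± 0.868), with none at Aqp4, Gfap and Gjb6. Unipolar brush cell genes had them at 8 of 10 (adjusted permutation p = 1), led by Calb2 (4.81 ± 0.297), Afap1l2 (4.44 ± 0.949), and Plcb1 (3.87 ± 0.487), with none at Lmx1a and Sln. Oligodendrocyte genes had them at 10 of 20 (adjusted permutation p = 0.692), led by the myelin genes Mbp (1.97 ± 0.127) and Cnp (1.34 ± 0.164), then Myrf (1.24 ± 0.00926) and Pdgfra (0.765 ± 0.0248), with none at Mobp and Sox10. Microglial genes had them at 4 of 20 (adjusted permutation p = 0.321), among them C1qc (0.912 ± 0.0493), Irf8 (0.492 ± 0.101) and Sall1 (0.392 ± 0.0653), with none at Csf1r, Cx3cr1 and P2ry12. Choroid plexus and ependymal genes had them at 4 of 14 (adjusted permutation p = 0.335): Foxj1 (3.64 ± 1.21), Otx2 (1.20 ± 0.361), Ccdc153 (0.868 ± 0.109) and Enpp2 (0.335 ± 0.0361).

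Promoter peaks in both libraries were also counted for the liver, muscle, lymphocyte, erythroid and keratinocyte lists, and none of these 5 lists passed the test in the main setting. Their random lists, matched on CpG, had means of 30.4%, 38.0%, 39.1%, 28.8% and 31.9% in that order, and erythroid genes lay near theirs, at 26.7%. Counts were 3 of 20 for liver (adjusted permutation p = 0.260), 3 of 20 for muscle (0.0552), 4 of 20 for lymphocytes (0.09999), 4 of 15 for erythroid cells (1) and 4 of 20 for keratinocytes (0.379), each value in parentheses an adjusted permutation p. Several of these peaks lay in windows shared with another gene: Foxa3 (6.37 ± 1.25) with Sympk, Actn3 (8.18 ± 2.43) with Zdhhc24, and Mylpf (4.90 ± 0.967) with Tbc1d10b. Ebf1 (6.82 ± 1.84), a factor of B cells that is also used in neurons, and Krt10 (4.67 ± 0.840) shared their windows with no other protein-coding gene. Non-coding genes were not checked for this. The Krt10 peak of replicate 1 (chromosome 11, 99385921 to 99386180) lay at an inner start, not at the outermost one (99389364). The same holds for Rora, Nfib, Lhx2, Tfap2a, Otx2 and Enpp2 among the genes named above, and this list is not complete. Alb, Apoa1, Myod1, Cd3e, Hba-a1 and Krt14 had no promoter peak in either library. Imprinted genes had promoter peaks at 21 of 27 (adjusted permutation p = 0.378), with a peak shared by Peg3 and Usp29 (6.42 ± 1.80) and another by Snrpn and Snurf (5.18 ± 0.960), and none at Igf2, Ndn and Dlk1. All 11 of 11 genes listed as escaping X inactivation had one (adjusted permutation p = 0.416).

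Of the 24 lists, 8 were called, 2 above and 6 below random lists. The calls for housekeeping and GABA interneuron genes did not hold in either library alone (adjusted permutation p = 0.0540 and 0.0528 for housekeeping, 0.203 and 0.223 for interneurons, with ranges over all alternatives of 0.0008 to 0.0612 and 0.000686 to 0.542). Some lists not called passed under CpG-matched alternatives. With the 500 bp window these were microglial (10%, adjusted permutation p = 0.0312), liver (5%, 0.0264), muscle (5%, 0.0016), lymphocyte (10%, 0.0096) and immediate early genes (100%, 0.0312), and with the shorter peak list oligodendrocyte (30%, adjusted permutation p = 0.0260), choroid plexus and ependymal (14.3%, 0.0377), lymphocyte (10%, 0.0158), synaptic (100%, 0.0236) and immediate early genes (100%, 0.0158). With the 2500 bp window, in contrast, liver (35%, percentile 48.6) and muscle genes (40%, percentile 40.9) lay near the middle of random lists. Microglial (20%, percentile 2.5) and lymphocyte genes (20%, percentile 0.59) stayed low there without passing. Among the stronger 50% of peaks, oligodendrocyte (15%, adjusted permutation p = 0.0012), lymphocyte (10%, 0.0380) and synaptic genes (100%, 0.0072) passed, and without replicate 1 muscle genes did (15%, 0.0315). Without matching on CpG, the calls for forebrain neuron genes (adjusted permutation p = 0.0542, the highest of its 8 alternatives, the lowest being 0.000686) and for hindbrain and midbrain patterning genes (0.307, the highest of 8, the lowest being 0.000686) were also lost. That setting gained 11 calls, among them liver (adjusted permutation p = 0.00107), muscle (0.0008), lymphocyte (0.00144), erythroid (0.0275) and keratinocyte genes (0.00175) below random lists, and synaptic (0.0008), circadian clock (0.00107) and X escape genes (0.0107) above them.

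**Figure D1:**
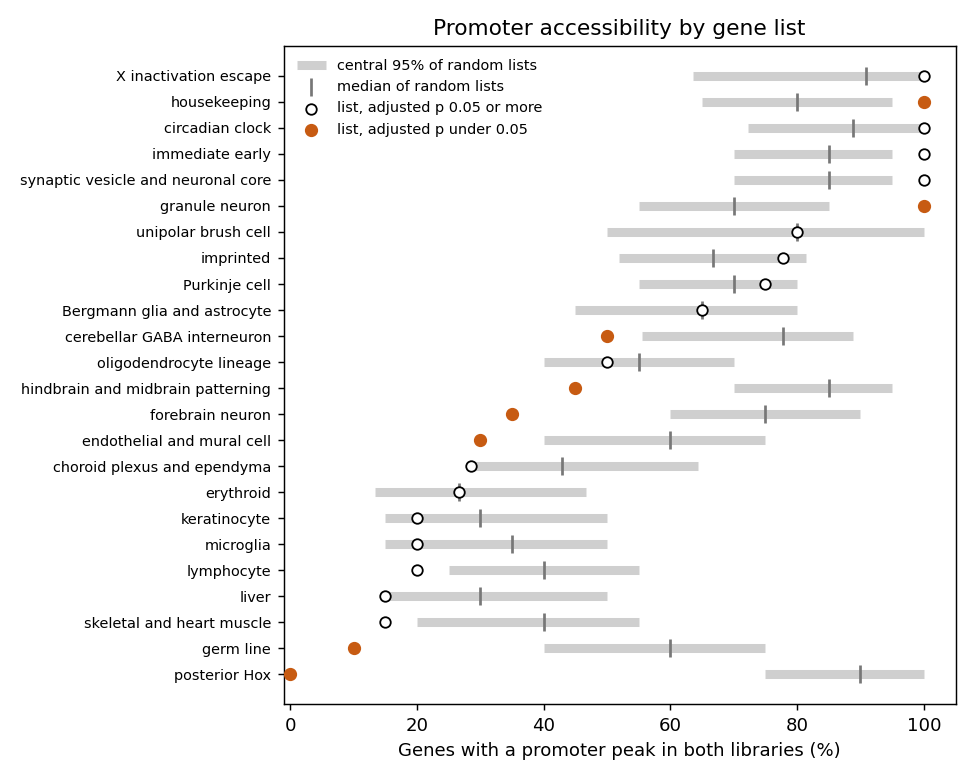
Share of genes with a promoter peak in both libraries, in percent (x axis), for 24 gene lists (y axis). Points are the lists, filled where the adjusted p was under 0.05, and grey bars span the central 95% of 10000 CpG-matched random lists with their median as a tick; granule neuron genes lie at 100% and posterior Hox genes at 0%.

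Accessible sites outside promoters were dense around granule neuron, immediate early, circadian clock and synaptic genes. Granule neuron genes had a median of 29.98 shared non-promoter peaks per 100 kb against 1.96 for length-matched random lists (adjusted permutation p = 0.0012, gene-label permutation with Benjamini-Hochberg adjustment over 24 lists), with 94.9 at Neurod2, 65.5 at Zic2, 43.2 at Cbln3 and 28.9 at Neurod1. Immediate early genes, which respond to neuronal activity, had 12.9 against 0, with 79.5 at Egr1 and 32.3 at Jund. Circadian clock genes had 9.90 against 2.03, with 51.8 at Per1 and 29.2 at Nr1d1, and synaptic genes had 7.46 against 2.18, with 41.7 at Rab3a and 16.7 at Vamp2 (adjusted permutation p = 0.0012 for each of these lists). Per1 and Vamp2 lie close together and their windows overlap, so that some peaks can count for both.

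Bergmann glia and astrocyte genes had 5.12 peaks per 100 kb against 2.06 (adjusted permutation p = 0.0499), with 9.41 at Nfib. That call was lost over the gene body alone (3.29, adjusted permutation p = 0.138), with 50 kb either side (4.28, adjusted permutation p = 0.134) and with the shorter peak list (3.01, adjusted permutation p = 0.106), in a range of 0.0343 to 0.138 over 6 alternatives. The calls of the other lists held under all alternatives, but their values moved: with the shorter peak list, granule neuron genes had 13.4, circadian clock genes 5.68 and synaptic genes 3.92, and with 50 kb either side granule neuron genes had 14.0 and immediate early genes 8.10. Other neuronal lists did not pass: Purkinje cell genes had 1.35 (adjusted permutation p = 0.611), GABA interneuron genes 1.22 (0.457), unipolar brush cell genes 2.705 (0.737) and forebrain neuron genes 2.49 (0.737). Without replicate 1 these last lists had 2.76, 4.90 and 4.10. Not called either were oligodendrocyte genes with 3.45 (adjusted permutation p = 0.382) and microglial genes with 3.56 (adjusted permutation p = 0.382). Imprinted genes had 4.45 (adjusted permutation p = 0.0520) and passed in 3 of 6 alternatives, with the shorter peak list (adjusted permutation p = 0.0288), without replicate 1 (6.76, 0.0328) and without length matching (0.0400). Housekeeping genes had 3.597 (adjusted permutation p = 0.423) and passed in 2 of 6, with 50 kb either side (5.54, 0.0317) and without replicate 1 (8.35, 0.0328). Of the 24 lists, 5 were called, all above random lists, and 19 did not pass the test.

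**Figure D2:**
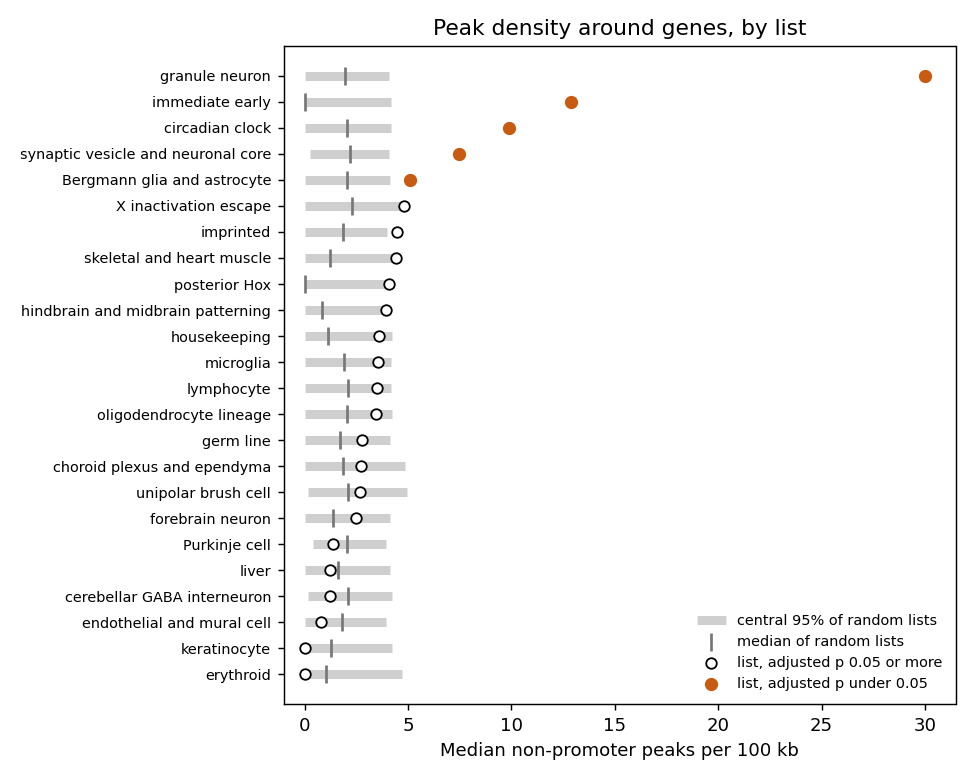
Median number of shared non-promoter peaks per 100 kb of gene body plus 10 kb either side (x axis) for 24 gene lists (y axis). Points are the lists, filled where the adjusted p was under 0.05, and grey bars span the central 95% of 10000 length-matched random lists; granule neuron genes lie at 29.98.

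Distal peaks were rich in the consensus of the insulator protein CTCF and in several other consensus sequences. Among 46161 shared distal peaks, 8.46% held the CTCF consensus, against 0.0563% of 79409 flanking windows, a ratio of 150.2 (95% interval 99.4 to 283). The E-box of the NeuroD and Atoh type, read by proneural factors, was present in 15.1% against 4.17% (3.61, 3.39 to 3.85). The sequence of the nuclear factor I (NFI) family was found as a single site in 19.5% against 7.503% (2.60, 2.499 to 2.71) and as a dimer in 0.123% against 0.0144% (8.55, 3.68 to 35.3). The ZIC sequence was present in 14.9% against 7.15% (2.08, 1.98 to 2.19) and the MEF2 sequence in 0.375% against 0.0892% (4.20, 3.09 to 5.86). Some forms of the CTCF consensus contain the ZIC sequence or the E-box of the NeuroD and Atoh type, and each sequence was counted on its own. How much of the ZIC and E-box shares comes from CTCF matches was not tested.

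Other sequences above their flanks were the RFX palindrome (ratio 8.02, interval 2.60 to 84.2, 15 peaks against 3 flanks, 5.25 without replicate 2), NRF1 (6.47, 2.44 to 40.5, 42 peaks against 4 flanks, 2.30 with flanks 5000 bp away and 21.2 among the stronger 50% of peaks), the cyclic AMP response element CRE (2.75), ROR (2.35), the LHX and homeobox sequence (1.59), AP-1 (1.57), POU (1.31), the E-box CAGCTG (1.23), TEAD (1.20) and SOX (1.04, interval 1.00 to 1.07). Sequences below their flanks were SP and KLF (0.693), PU.1 (0.868) and the TATA box (0.918). In all, 19 of 28 sequences were called, 16 above and 3 below. Distal peaks had a median GC content of 52.98% against 45.7% in unmatched flanks, and without matching on GC the ratios of LHX and homeobox (0.465), POU (0.554), SOX (0.771), SP and KLF (2.06) and PU.1 (1.06) turned to the other side of 1, and that of MEF2 fell to 1.502 (1.23 to 1.86). Among the stronger 50% of peaks, 12 sequences were called, all above their flanks. The calls of RFX, SOX, POU, TEAD and the TATA box were lost there, those of RFX and SOX also with flanks 5000 bp away (RFX 2.00, interval 0.822 to 7.54), and those of SOX and PU.1 with flanks matched on CpG number. The lower calls of PU.1 and of SP and KLF were lost among these stronger peaks and with windows of 150 bp either side (0.939 and 0.975), that of PU.1 also without replicate 2 (0.921, 0.816 to 1.04), and the CTCF ratio, though always above 1, was 67.1 with those windows.

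**Figure D3:**
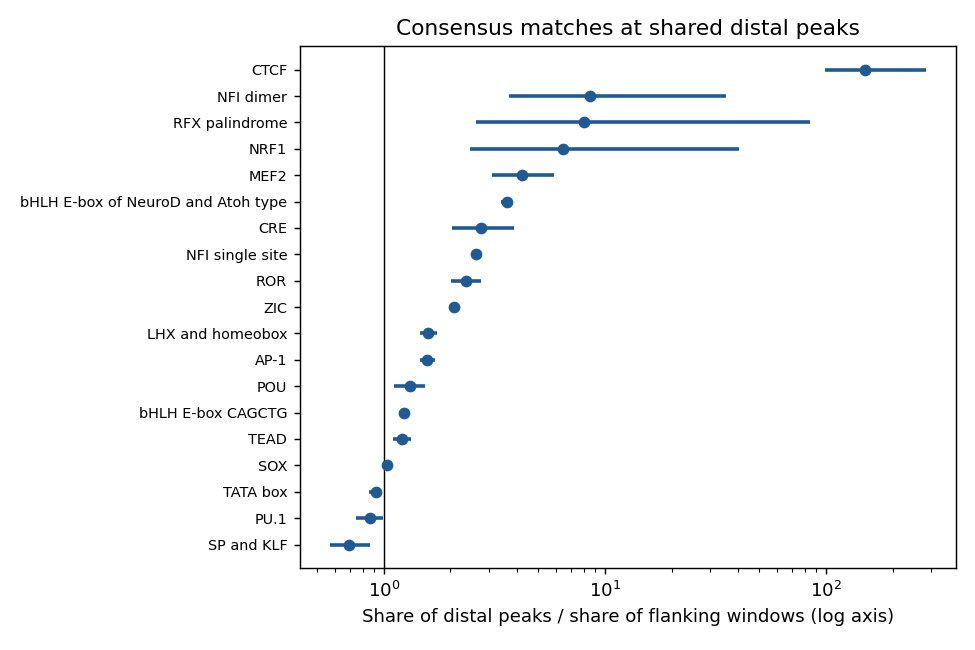
Share of shared distal peaks with a consensus match divided by the share of GC-matched flanking windows (x axis, log scale) for the 19 called sequences (y axis). Points are ratios and lines are 95% bootstrap intervals; CTCF lies at 150.2 and SP and KLF at 0.693.

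Footprints were examined inside all peaks of each library, promoters included, so their ratios cannot be compared directly with those of distal peaks. Some sequences were above 1 in both. LHX and homeobox, ROR, POU, AP-1 and SOX were above 1 in distal peaks and below 1 in footprints, and SP and KLF went the other way. Replicate 1 held 329023 footprints and replicate 2 held 358227, with a median width of 10 bp, and 78.1% and 75.7% of peaks held at least 1. Of the footprints inside peaks, 49.1% ± 3.14 (SD, n = 2) overlapped one of the other library, against at most 30.3% in 100 placements within the same peaks. Against windows of the same width in the same peaks, footprints had high ratios, with overlapping intervals, for CTCF (37.4, 95% interval 32.2 to 44.8), NRF1 (35.5, 21.8 to 75.3) and the NFI dimer (34.6, 17.2 to 155), which rests on 5 control matches and was 73.0 in replicate 1 and 24.0 in replicate 2. Lower ratios above 1 were found for RFX (11.2), CRE (8.75) and SP and KLF (5.80), followed by the E-box of the NeuroD and Atoh type (2.20), the NFI single site (2.01), YY1 (1.94), HNF4A (1.63), ZIC (1.60), EBF (1.60), ETS (1.30), the E-box CACGTG (1.24) and the E-box CAGCTG (1.22). Lower in footprints were GATA (0.625), PU.1 (0.648), LHX and homeobox (0.678), the TATA box (0.714), POU (0.724), ROR (0.769), SOX (0.784) and AP-1 (0.938). MEF2 was not called (0.99961, 0.818 to 1.25). With no added bases the ratios moved strongly, to 583 for CTCF (12 control matches), 33.7 for CRE, 23.1 for SP and KLF and 0.274 for MEF2, and the call of HNF4A was lost (1.24, 0.643 to 2.35), as was that of AP-1 without replicate 1 (0.963, 0.896 to 1.03). The control windows were not matched on GC content, and DNase I itself cuts some sequences more readily than others, which these ratios do not correct. As in distal peaks, ZIC and E-box matches that lie within CTCF matches were not set apart.

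The X chromosome carried fewer and weaker peaks than any autosome. Both libraries are from females, which have a pair of X chromosomes. There were 17.4 peaks per Mb on X, against 31.8 to 71.6 on the 19 autosomes (median 47.8), so that X had 0.365 ± 0.0140 times the autosomal median (SD, n = 2) and ranked lowest of 20 chromosomes in both libraries. The share of protein-coding genes with a promoter peak was 47.7% on X and 51.4% to 73.3% on autosomes, and the median peak signal was 0.519 on X and 0.664 to 0.949 on autosomes. X holds 5.80 coding genes per Mb, while chromosome 12, with 5.50 per Mb, had 38.0 peaks per Mb. Genes listed as escaping X inactivation had strong promoter peaks on X, with signals of 19.1 ± 6.73 at the histone demethylase gene Kdm6a, 10.6 ± 3.25 at Ftx, 8.44 ± 1.08 at Kdm5c and 7.98 ± 1.74 at Ddx3x (SD, n = 2). Among the stronger 50% of peaks, the ratio of X to the autosomal median was 0.263.

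**Figure D4:**
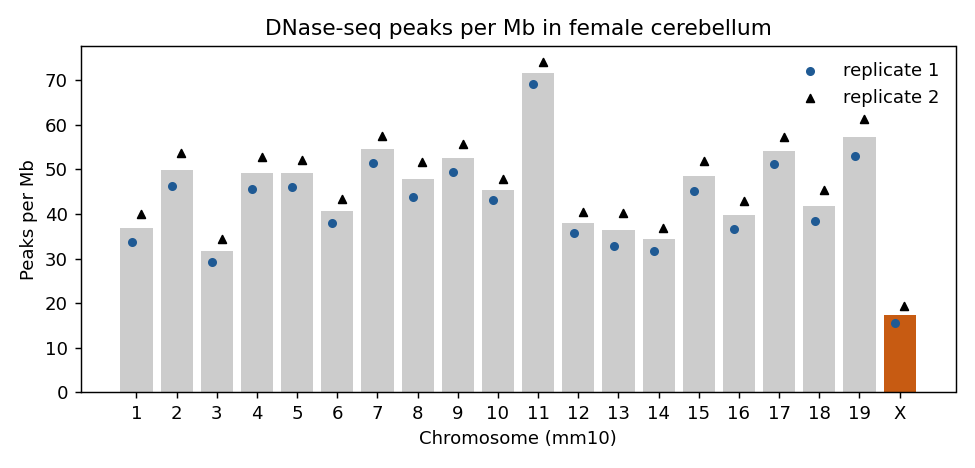
Peaks per Mb of sequence (y axis) on each mm10 chromosome (x axis). Bars are means of both libraries and markers the separate libraries; X, in orange, lies at 17.4 and the autosomes lie at 31.8 or more.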

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

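All tests in this part except the search for sequence copies over all Y peaks were chosen after the result was seen. Peaks were called on the Y chromosome although both libraries are from female mice, which places them outside the measurements reported for the autosomes and X: 30 peaks in replicate 1 and 35 in replicate 2. The strongest lay at chromosome Y, 90744601 to 90744820, with a signal of 17.1 in replicate 1 and 6.62 in replicate 2, and 15 and 6 of the peaks lay within 100 kb of it, from 90717638 on.

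Reads from male cells are argued against, since 0 of the 4 promoters of Ddx3y, Uty, Kdm5d and Eif2s3y held a peak in either library, while the promoters of their X copies Ddx3x, Kdm6a, Kdm5c and Eif2s3x did in both, with 908 to 3048 signal steps. Sequence shared with other chromosomes may account for the scattered peaks: 95.5% of the 44 peaks away from the strongest had a copy off the Y chromosome (95% identity over 80% of the length), against 20.6% of 325 random Y windows of the same widths. In the cluster around the strongest peak this share was 23.8% of 21 peaks. This argues against sequence shared with the assembled chromosomes at this identity as the whole source there. Sequence missing from the assembly, or particular to the CAST strain, could not be searched, so shared sequence of that kind stays open. Over all 65 peaks the share with a copy was 72.3%, which decides neither way. The strongest peak itself is among those with a copy, on chromosomes 7 and X, so that shared sequence stays open for it, as does what gives the rest of the cluster its signal, and no biological explanation was tested because the design holds 1 group.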

How the results depend on the processing

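Of 43 recomputed values of the 10 main results, 31 were counted as unchanged, and the cause of the other shifts was not tested unless stated. For gene lists and motifs, unchanged means only that a similar number was called, whichever lists or motifs those were. The 2500 bp window, with 6 called lists against 8, counts as unchanged although the housekeeping and GABA interneuron calls were lost. For the other results it means the same side of the test or a value within the spread. The flanks matched on CpG number were chosen after seeing the data; all other alternatives were fixed before. The overlap of peaks stayed above chance under all 4 alternatives. The promoter share of peaks was 19.2% and 39.2% with windows of 500 and 2500 bp, 34.2% with the shorter lists, 37.8% for the stronger 50% of peaks, and 26.6% to 29.1% with either replicate left out. The signal correlation was 0.977 on the linear scale. The X ratio was 0.263 for the stronger 50% of peaks and 0.354 to 0.374 with either replicate left out. The share of library-specific peaks was 43.3% with 50% reciprocal overlap and 18.9% with the 500 bp rule. Called promoter lists numbered 13 with the 500 bp window, 13 with the shorter lists and 16 without CpG matching, against 8, and 6 to 7 with either replicate left out; called density lists numbered 4 to 7 over all alternatives, against 5. Called distal motifs numbered 12 for the stronger 50% of peaks, which leaves fewer windows, against 19, and 18 to 19 with either replicate left out; called footprint motifs numbered 23 to 24, against 23. Without GC matching of the flanks, 9 distal motifs called in at least 1 of the settings changed side: SOX 0.771, ETS 1.58, PU.1 1.06, REST 1.34, SP and KLF 2.06, LHX and homeobox 0.465, CACGTG 1.32, POU 0.554 and EBF 1.51. Of 192 recomputed promoter shares of single lists, 158 kept their side of the test, as did 136 of 144 densities and 71 of 77 footprint ratios. Values not called in either setting also lay on the other side of random lists or of 1 under some alternatives, such as the share of imprinted genes with the outermost starts (percentile 33.7 against 91.03). No paired analysis was possible because there is 1 group.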

Other observations

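All tests in this part except the searches for mitochondrial and for repeated nuclear sequence and the count of peaks per Mb of unmasked sequence were chosen after the results were seen. Among 11529 protein-coding genes with a promoter peak in both libraries and a mean signal of at least 1, 99.8% lay within 2-fold of the median ratio between the pools. Where the same region was compared in both, Gabra6, which encodes a receptor subunit typical of granule neurons, had a signal of 1.46 in replicate 1 and 2.63 in replicate 2 (log2 ratio to the median -1.25), and Cnep1r1 had 5.35 and 9.57 (-1.24). In the other direction, the patterning gene En1 had 2.46 and 0.878 (1.08) and Gm21887, on X at 170009841 to 170010160, had 26.8 and 11.1 (0.86). At Nelfb the strongest promoter peaks were different regions, with 0.407 in replicate 1 and 3.84 in replicate 2, and no peak was listed at 25211321 to 25211540 on chromosome 2 in replicate 1. These are values of 1 library each, with no replicate check, and the genes were chosen after their values were seen.

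By gene list, the median log2 ratio relative to that of all promoters ran over 15 lists from -0.22 for oligodendrocyte genes (3 of 10 above 0) and -0.21 for forebrain neuron genes (2 of 7 above 0) to 0.14 for hindbrain and midbrain patterning genes (7 of 9 above 0) and 0.18 for circadian clock genes (13 of 18 above 0). Granule neuron genes lay at -0.04 (9 of 20 above 0). A gene-label permutation was also run on these lists, in which none passed after adjustment, and is not used as a test of the pools, since each has 1 library.

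Over all protein-coding genes, those with the most shared non-promoter peaks, chosen after their values were seen, were Parp3 (112.7 per 100 kb), Leng8 (99.6), Gpr62 (95.6), Neurod2 (94.9), Shf (94.4), Fkbpl (88.1) and Uncx (85.1). The windows of Parp3 and Gpr62 adjoin on chromosome 9, as do those of Leng8 and Ttyh1 (69.7) on chromosome 7, so that peaks are counted for more than 1 gene. The homeobox gene Barhl2, a member of the granule neuron list, had 77.99.

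The X chromosome pattern was weighed against 3 explanations. Lower gene density as the whole cause is argued against, since X had 3.01 peaks per coding gene (2.68 and 3.33 in the libraries), under the lowest autosome in each (3.61 and 4.03). More repeated sequence as the whole cause is also argued against: 46.8% of X is masked as repeat against 30.6% to 35.8% of autosomes, yet X had 32.7 peaks per Mb of unmasked sequence (29.2 and 36.3), under the lowest autosome (45.3 and 53.5). As a hypothesis, the values are consistent with X inactivation leaving 1 accessible copy of the pair: promoter signals of 434 X genes with peaks in both libraries had a median of 0.528 times that of autosomal genes of the same CpG decile (0.860 to 1.19 for single autosomes), while the 11 genes listed as escaping inactivation had 1.09, above all of 10000 CpG-matched random lists of X genes. The escape list includes non-coding genes such as Ftx, whereas its random lists held protein-coding X genes only. Without separate allele counts or male libraries, which were not analysed here, a share of X promoters below detection for other reasons stays open.

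The strongest distal regions were weighed against 3 technical explanations. Mitochondrial sequence is argued against, since 0 of the 10 regions matched the mitochondrial genome at 80% identity over 50% of the length. Other repeated nuclear sequence may explain 2 of the 10, the regions near Gm8797 (12 copies) and Igf2bp3 (2 copies), and transcription starts missing from the annotation may explain 4 of the 10, the CpG islands near Foxk1, Ptma, C87436 and Zfp239, of which the last lies 62 bp from a RefSeq start of Gm38882. The regions in the 3′ UTRs of Lars2 and Cers5 and those near Vps37c and Txn2 were covered by none of these, and copies below 95% identity were not searched. Ribosomal RNA sequence, which the strongest peak of each library overlapped, was not searched as such. Sequence missing from the assembly could not be searched, so repeated sequence of these kinds stays open for these regions.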
